A study of Mus musculus with 24 samples.

How the data were processed

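ATAC-seq libraries of mouse embryonic stem cells were compared across 4 lines and 6 times after doxycycline. Per the labels' protocols, the cells were grown on gelatin with LIF and with inhibitors of MEK (PD0325901) and GSK3 (CHIR99021), doxycycline was added the day after seeding, and libraries were made by the Omni-ATAC protocol. The lines were a wild type control, a wild type line with an inducible Firre transgene, a Firre knockout control and a Firre knockout line with the inducible transgene. Each line had 1 library at 0, 30, 60, 90, 120 and 150 min, so 24 libraries are described in the labels. Counts of 23 libraries were analysed, and the wild type Firre line at 60 min was not analysed here.

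The deposited table holds raw counts, whole numbers per consensus peak and library with no normalization by the authors. The deposited peak annotation gives positions and other values for 145143 peaks, including the signed distance in bp to the nearest annotated transcription start site (TSS), with gene names as the authors' file pairs them. Per the submitters' processing notes, the build was mm10 and the tools included MACS2 2.2.7.1 and featureCounts. The aligner, the treatment of duplicates, the shift of reads for the transposase and the annotation release are not given in the sources used here. No label describes separate cultures within a line and time, so the p-values measure the spread between libraries of 1 line each and cannot separate genotype from clone.

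Total counts in peaks ran from 5725518 to 14977148 per library, with a median of 7664147. A count of 0 in a library of median size allows up to 0.391 CPM, counts scaled to the library size, from a floor of 3 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

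Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, in its current rather than its legacy mode, which has to be requested in this version). Library sizes were scaled by TMM, and filterByExpr with a minimum of 10 counts and the lines as groups kept 129515 peaks. The p-values were adjusted by Benjamini-Hochberg over the tested peaks, and an adjusted p of 0.05 or less was called. Standard errors (SE) of log2 fold changes were derived from the F statistic. All 23 libraries shared 1 estimate of the spread. The time fit held line, time and transgene by time (9 residual degrees of freedom), so that the knockout and wild type backgrounds were the replicates of the Firre response. The line fit held line and time (14), and the slope fit held a linear slope per hour within each background (11). A slope shared by both backgrounds (13) and the difference of the transgenic line contrasts between backgrounds were added after the data were seen. CPM values are on TMM library sizes.

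The fits were tested on simulated counts drawn from the means, totals and spread of the real libraries, with peaks of a mean of at least 20 counts changed by 1.5-fold (67 peaks), 2-fold (67) or 4-fold (66) per comparison. For slopes the fold was per hour. At 2-fold, 94% of the changed peaks were recovered for the knockout against wild type contrast, 89.6% for the transgenic line in the wild type background, 97% for the shared slope, 88.1% for the slope in the knockout background and 47.8% for the mean Firre response. At 1.5-fold the mean Firre response recovered 7.5%. Unchanged peaks made up 4.1% to 7.34% of the calls. The simulated peaks were drawn independently, with a spread set by abundance and no structure between libraries. These rates therefore need not hold for the real libraries. There, shuffled times called up to 2758 peaks for the shared slope and 1327 for the time course. Other splits of the control libraries called up to 3619.

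Gene lists were tested with camera of limma 3.58.1 on promoter peaks, within 1000 bp of an annotated TSS of a list gene or in its promoter annotation, against the other promoter peaks. The preset correlation was 0.01, an estimated correlation was the check, and Benjamini-Hochberg adjustment ran over the 14 lists with measured peaks. The lists were naive pluripotency, formative and primed pluripotency, germ layer and trophoblast markers, 2-cell-like genes, fibroblast markers for feeder cells, immediate early genes, ERK pathway targets, Wnt pathway targets, LIF and STAT3 targets, integrated and mitochondrial stress, heat shock, p53 targets, genes in nuclear contact with the Firre locus, the X inactivation region and imprinted genes. Of the 10 genes in the 2-cell-like list, 0 had a tested promoter peak, so that list was not tested. Cyr61, Ctgf and Nespas were matched as Ccn1, Ccn2 and Gnasas1 through a RefSeq table of assembly GRCm38.p6, used for names alone.

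The groups, tests, gene lists, named peaks and first set of alternatives were fixed before the data were examined. Named per comparison and direction were the 6 called promoter peaks and the 6 other called peaks with the largest change, skipping peaks with a mean under 10 counts per library. For the mean Firre response, peaks whose sign differed between the backgrounds were skipped as well. Where none was called, the 3 peaks per direction with the smallest p were taken and are said not to pass. Every peak in the Firre gene and members of the lists could also be named. Peaks on a chromosome with a median line difference above 0.2 on the log2 scale were to be named only as part of that chromosome. None of chromosomes 1 to 19 and X reached that. The rule was not applied to unplaced contigs or to the mitochondrial genome, whose peaks differed by 0.33, 1.21 and 0.33 between the control lines. The alternatives were DESeq2 1.42.0, limma-voom, the legacy mode of edgeR, DESeq2 size factors, total counts without a composition factor, loess offsets on abundance, no filter and a minimum of 50 counts, another baseline, a late minus early difference, line contrasts without time or without the 0 min libraries, autosomes alone, a promoter window of 3000 bp, and leaving out each library in turn. After the data were seen, fits without chromosome 11, without the knockout control libraries of 30 and 90 min, and with the share of counts in promoter peaks as a covariate were added. Correction for GC content was not run, since no genome sequence was used here. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.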

Results

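Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in mouse embryonic stem cells after the long noncoding RNA Firre was induced with doxycycline. Inducible lines were compared with control lines, described as genetically matched, that also received doxycycline. The aim was to tell the effect of Firre from that of the drug. The wild type control, knockout control and knockout Firre line each had 6 libraries, and the wild type Firre line had 5, since its 60 min library was not analysed here. Counts fell in 145143 consensus peaks with a median width of 734 bp. Total counts per library ran from 5725518 to 14977148. The highest total, in the wild type Firre line at 90 min, stood apart from the next in that line, 8314720. The first 3 principal components held 19.2%, 6.5% and 5.4% of the variance, and the knockout control libraries of 30 and 90 min lay apart from the others on the first.

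The Firre gene was nearly empty of counts in both knockout lines, apart from 1 exonic peak. Of 19 peaks annotated to Firre on the X chromosome (mm10), 18 were lower in the knockout control than in the wild type control. Together these 18 peaks had 87.6 ± 6.95 CPM (SD, n = 6) in the wild type control and 1.42 ± 0.92 CPM (n = 6) in the knockout control, which is 1.62% of the wild type level. They had 99.6 ± 10.04 CPM (n = 5) in the wild type Firre line and 3.68 ± 0.80 CPM (n = 6) in the knockout Firre line. In 10 of the 19 peaks the 6 knockout control libraries held 0 counts in total. One of these, in intron 8 of 19 (X:50602462-50603254), had 7.31 ± 0.72 CPM in the wild type control, while 0 counts in the knockout control allow up to 0.0612 CPM over the group.

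The peak that differed lies in exon 18 of 20 of Firre (X:50569280-50570236). Its level was 2.04 ± 0.47 CPM in the wild type control, 7.19 ± 2.26 CPM in the knockout control, 17.4 ± 3.80 CPM in the knockout Firre line (n = 6 each) and 25.4 ± 8.89 CPM in the wild type Firre line (n = 5). The log2 difference was 3.71 ± 0.28 (SE) between the wild type Firre line and its control (edgeR adjusted p = 6.44e-06) and 1.21 ± 0.22 between the knockout Firre line and its control (edgeR adjusted p = 0.018). The knockout control was above the wild type control by 1.89 ± 0.36 (edgeR adjusted p = 0.00409), a call that ended when the share of counts in promoter peaks was a covariate. The annotated promoter peak of Firre (X:50634917-50635918) was also higher with the transgene, at 14.2 ± 1.18 against 9.41 ± 0.77 CPM in the wild type background and 2.48 ± 0.52 against 0.88 ± 0.57 CPM in the knockout background.

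**Figure D1:**
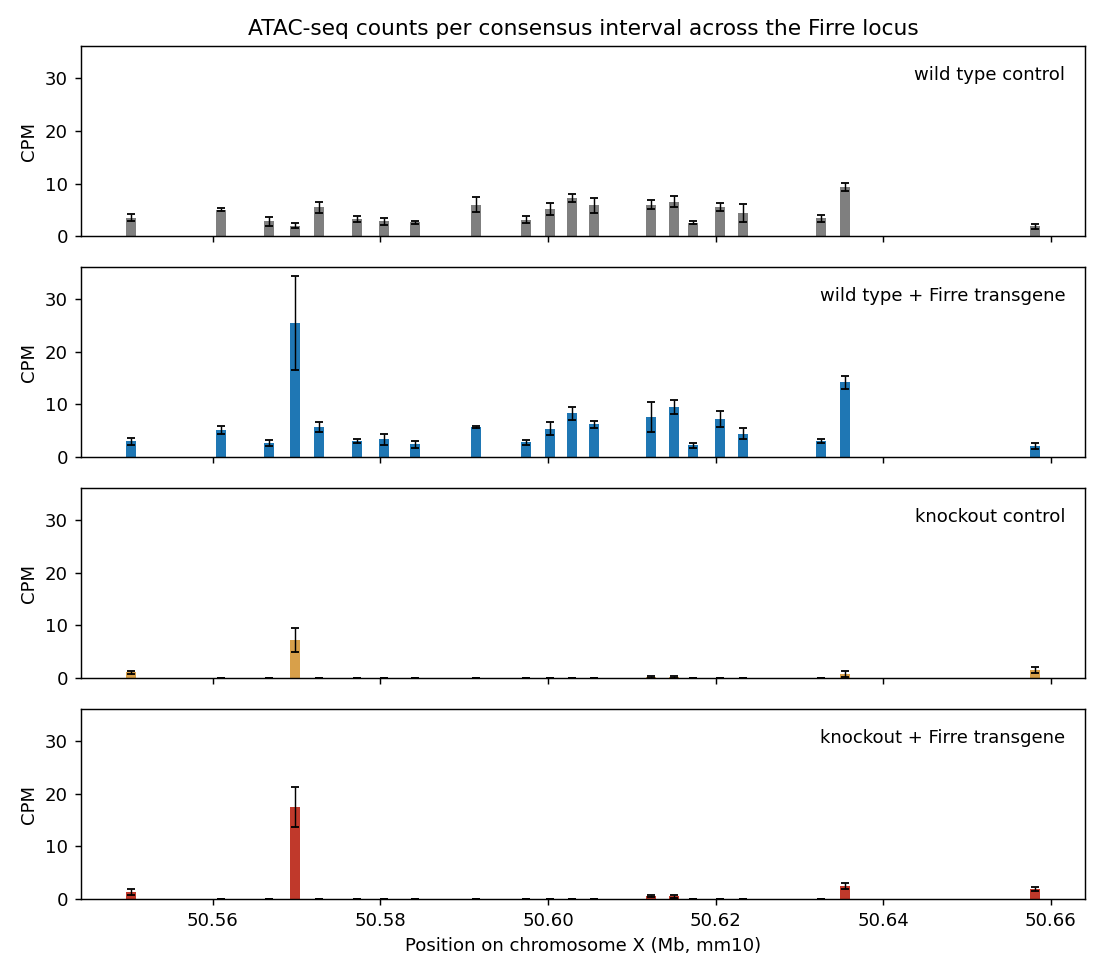
Mean CPM of each consensus peak (bars, with SD over libraries of a line) against its position on chromosome X in Mb (mm10), 1 panel per line. The exonic peak reaches 25.4 CPM in the wild type Firre line and 17.4 CPM in the knockout Firre line, where most other Firre peaks are near 0.

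After induction, the exonic Firre peak was the single peak whose time course differed between Firre and control lines. In the wild type Firre line it went from 12.9 CPM at 0 min to a mean of 28.6 ± 6.30 CPM afterwards (SD, n = 4 times), and in the knockout Firre line from 12.5 to 18.4 ± 3.27 CPM (n = 5). The control lines went from 2.27 to 2.00 ± 0.51 CPM and from 8.15 to 6.99 ± 2.47 CPM (n = 5 each). The time course test gave an edgeR adjusted p = 0.00059, and at 90 min the response was 1.86 ± 0.33 on the log2 scale (edgeR adjusted p = 0.0147). DESeq2 called 0 peaks in either test, and the exonic peak passed neither test without the knockout control libraries of 30 and 90 min, where the time course called 8 other peaks. Without the knockout control library of 0 min or of 30 min, the time course called 0 peaks. It called 2 without the knockout control at 90 min or the knockout Firre line at 0 or 30 min, 4 without the wild type control at 150 min and 7 without that at 90 min.

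No peak passed for the mean Firre response over 30 to 150 min by edgeR, with 0 calls by DESeq2 and 1 by limma-voom. Of 129515 peaks, 4884 (3.77%) had an unadjusted p under 0.05, where chance gives about 5%. The peak with the smallest p lies in intron 1 of 3 of Pde6d, which encodes a prenyl-binding protein (1:86549363-86551159, 23524 bp from the nearest TSS, that of Ptma), with a log2 response of 1.08 ± 0.21 (edgeR adjusted p = 0.0819). The exonic Firre peak had 1.16 ± 0.25 and a peak in intron 1 of 2 of Apod, a lipocalin gene (16:31299422-31301637), had 0.78 ± 0.17 (edgeR adjusted p = 0.464 each). The 3 negative peaks with the smallest p were at Gm11704 (-1.57 ± 0.35), Rev1 (-2.47 ± 0.62) and Gm4869 (-1.93 ± 0.49), and none passed. The mean response called 1 peak when the knockout control at 150 min, the knockout Firre line at 60 min or the wild type Firre line at 0 min was left out, and at most 2 peaks under any alternative.

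At single times edgeR called 0 peaks at 30, 60, 120 and 150 min. There 4720, 4746, 5083 and 8229 peaks had an unadjusted p under 0.05 (3.64%, 3.66%, 3.92% and 6.35%). DESeq2 called 0 at these times, and limma-voom called 0, 0, 0 and 1. The 60 min response rests on the knockout background alone. Linear slopes within the knockout background, within the wild type background and their difference gave 0 calls by edgeR, DESeq2 and limma-voom. An unadjusted p under 0.05 was found at 7448, 4931 and 6043 peaks (5.75%, 3.81% and 4.67%). The slope in the knockout background called 2 peaks without the knockout control at 0 min. The sign of the response was the same in both backgrounds for 48.8% of all tested peaks and for 46.4% and 44.2% of the 500 peaks with the smallest p in the knockout and wild type backgrounds. None of the 14 gene lists passed for the mean Firre response (smallest adjusted p = 0.555), including the genes described as nuclear contacts of the Firre locus, of which 2 of 5 were measured (median log2 0.06, adjusted p = 0.695).

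In the control lines, no peak was called after doxycycline. The time course and the mean response of the control lines gave 0 calls by edgeR, by DESeq2 and by limma-voom. An unadjusted p under 0.05 was found at 6560 and 6821 peaks (5.07% and 5.27%). In the mean response, the peak with the smallest p was lower, 6236 bp from the TSS of Plekhb2 (1:34883264-34884521, -0.90 ± 0.19, edgeR adjusted p = 0.609). Among higher ones it lay at -8270 bp from the TSS of Sertm1 (3:54922940-54923663, 0.74 ± 0.19, edgeR adjusted p = 0.746). The control time course called 2 peaks without the wild type control at 150 min and 9 without that at 90 min. No gene list passed (smallest adjusted p = 0.142).

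The Firre knockout control differed from the wild type control at many more called peaks than any induction, but the tests differed in power. The median SE was 0.163 on the log2 scale for this contrast and 0.317 for the mean Firre response. In simulated counts, 73.1% and 7.5% of peaks changed by 1.5-fold were recovered. Outside Firre, the knockout line was higher across chromosome 11, under every setting run, and at promoter peaks in general, where the median turned from 0.09 to -0.01 with the promoter share as a covariate. Chromosome 11 had a median log2 difference of 0.14 (0.052 under total counts), and 17.0% of its 9899 tested peaks were called, 1652 higher and 35 lower. Its median per library, against the wild type control mean, was 0.16 ± 0.03 (SD, n = 6) in the knockout control, 0.09 ± 0.03 (n = 6) in the knockout Firre line and -0.02 ± 0.02 (n = 5) in the wild type Firre line. Among named promoters on that chromosome was Mgat1 (11:49243404-49244818), which encodes an N-acetylglucosaminyltransferase of N-glycan synthesis. It had 45.7 ± 4.48 CPM in the wild type control and 81.0 ± 15.5 CPM in the knockout control (log2 0.82 ± 0.09, edgeR adjusted p = 2.65e-12), a call that ended with the promoter share as a covariate.

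**Figure D2:**
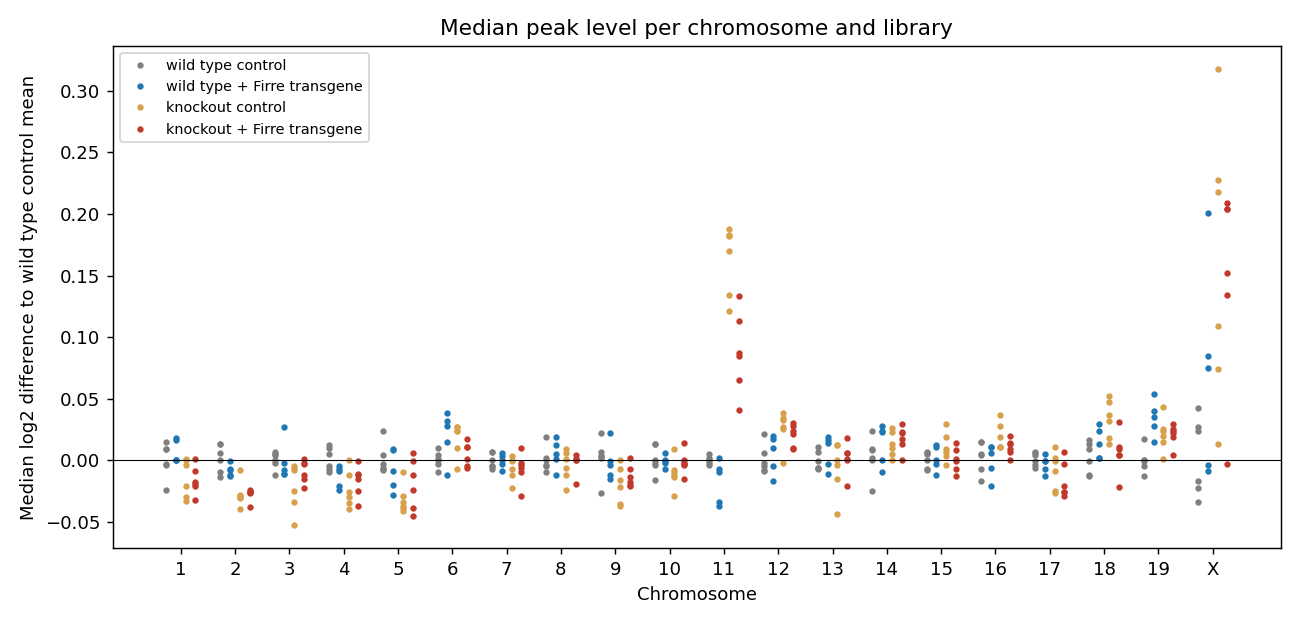
Median log2 difference of the tested peaks of each chromosome to the wild type control mean (vertical axis), 1 point per library, for chromosomes 1 to 19 and X (horizontal axis) and coloured by line. Chromosome 11 lies higher in both knockout lines (mean 0.16 and 0.09), and the X chromosome is spread widely in the knockout control (0.01 to 0.32).

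In all, edgeR called 10323 peaks between the control lines, 7128 higher and 3195 lower in the knockout line. Promoter peaks made up 3568 of the higher and 303 of the lower calls, with a median log2 difference of 0.09 for promoter and -0.05 for other peaks. The share of counts in promoter peaks was itself higher in the knockout control (41.7% ± 0.945, n = 6) than in the wild type control (38.6% ± 0.584, n = 6). With that share as a covariate, 53 peaks were called. Other settings called 6074 (DESeq2), 6293 (loess offsets) and 2134 (without the knockout control at 30 and 90 min). The higher calls were 69% of all by the main scaling, 36% under scaling by total counts, 56% under loess offsets and 57.1% under the stricter filter. Leaving out 1 library gave 5253 (knockout control 90 min), 5906 (wild type control 90 min), 6109 (knockout control 120 min), 6611 (knockout control 30 min) and 17208 (knockout control 150 min). The p-values measure the spread between libraries of 1 line each.

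Other peaks named between the control lines were mostly at predicted or noncoding genes. Higher in the knockout line were the promoters of Gm32885 (log2 0.99 ± 0.17), Gm15583 (0.90 ± 0.20), Gm49695 (0.85 ± 0.23) and Gm48407 (0.75 ± 0.14), and peaks in introns of Fnbp1 (1.22 ± 0.27) and Dop1b (1.18 ± 0.25). Lower were the promoters of Gm19880 (-1.24 ± 0.24), Gm47465 (-1.17 ± 0.28), Mir7083 (-1.16 ± 0.30) and Gm14233 (-1.11 ± 0.28). The calls at these promoters and introns ended with the promoter share as a covariate, that of Gm49695 also without the 0 min libraries, the knockout control at 0 min or the wild type control at 90 min, that of Gm15583 without the knockout control at 30 and 90 min, and that of Mir7083 without the wild type control at 150 min. An intergenic peak at 10:28997735-28998078 had 0 counts in the wild type control and 1.58 ± 0.53 CPM in the knockout control. It stayed called with the covariate, as did a mitochondrial peak at mt-Tr (1.21 ± 0.24), a promoter only by its annotation label, and an intergenic peak at 14:87940927-87941329 (1.15). The mt-Tr call ended under loess offsets.

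Among gene lists, promoter peaks of LIF and STAT3 targets and of imprinted genes were higher in the knockout control, where the promoter share was also higher. Over all promoter peaks, 3568 of 21777 were called higher, with a median of 0.09. Of 14 peaks of LIF and STAT3 targets, 6 were called higher (8 adjusted over the list alone), among them Stat3 (0.53 ± 0.09), Pim3 (0.43 ± 0.10) and Socs3, a feedback inhibitor of the pathway (0.27 ± 0.09). The median was 0.24 (camera adjusted p = 0.022), but 0.03 under loess offsets and -0.04 with the promoter share as a covariate, and adjusted p = 0.696 with an estimated correlation. Of these peaks 5 lie on chromosome 11, and without that chromosome the median was 0.24 (camera adjusted p = 0.0214, or 0.993 with an estimated correlation). The list shares Klf4, Klf5 and Tfcp2l1 with naive pluripotency. It also passed in simulated counts where naive pluripotency alone was raised, by 1.3-fold (camera adjusted p = 0.000234). Of 19 peaks of imprinted genes, 7 were called higher (9 adjusted over the list alone), at Gnasas1 (0.53 ± 0.09), Grb10 (0.47 ± 0.09), Impact (0.46 ± 0.08), Plagl1, Nnat, Peg10 and Zim1. Their median was 0.21 (camera adjusted p = 0.022) and stayed positive under every setting run, from 0.11 to 0.25, with adjusted p = 0.277 with an estimated correlation. Of the 19 peaks 1 lies on chromosome 11, that of Grb10. Without it the median was 0.20 (camera adjusted p = 0.0214, or 0.486 with an estimated correlation).

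The other lists did not pass between the control lines in the 1000 bp window, while heat shock, Wnt pathway and naive pluripotency genes passed with 3000 bp (adjusted p = 0.00687, 0.00151 and 0.0149; 0.623, 0.221 and 0.815 with an estimated correlation). Of 20 peaks of naive pluripotency genes, 6 were called higher (7 adjusted over the list alone), among them Esrrb (0.41 ± 0.09) and Klf5 (0.35 ± 0.09), with a median of 0.15 that turned to -0.05 under loess offsets (camera adjusted p = 0.12). Heat shock genes had 3 of 9 called higher (6 over the list alone; median 0.24, 0.00 under loess offsets, adjusted p = 0.0865, and 0.0387 without chromosome 11, or 0.993 there with an estimated correlation). Wnt pathway targets had 2 of 7 called higher, Axin2 (0.65 ± 0.08), a feedback inhibitor, and Rnf43 (0.54 ± 0.11), both on chromosome 11 (3 over the list alone; median 0.17, adjusted p = 0.0876). Integrated and mitochondrial stress genes had 3 of 13 called higher (4 higher and 2 lower over the list alone; median 0.15, -0.04 under loess offsets, adjusted p = 0.59). Immediate early genes had 2 of 20 called higher, Egr1 and Klf6 (median 0.15, -0.06 under loess offsets, adjusted p = 0.568), and p53 targets 2 of 11, Sesn1 and Ccng1 (median 0.11, -0.10 under loess offsets, adjusted p = 0.711). Formative and primed pluripotency had 2 of 17 called higher (Dnmt3a and Wnt8a), and 1 each was called for germ layer and trophoblast markers (Pax6, of 17), fibroblast markers (Fn1, of 12) and ERK pathway targets (Egr1, of 12), with adjusted p = 0.89 for each list. Their medians were 0.07, 0.10, 0.08 and 0.05, and under loess offsets -0.09, -0.02, 0.06 and -0.13. Since 3568 of all 21777 promoter peaks were called higher, a few called members do not set a list apart. The X inactivation region (7 peaks, median 0.20, adjusted p = 0.767) and the nuclear contacts of Firre (5 peaks, median -0.03, adjusted p = 0.733) had 0 called by edgeR over all peaks.

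The knockout Firre line differed from its control at 1183 peaks by edgeR, 737 higher and 446 lower. The largest named change was higher, in an intron of Rapgef4, an exchange factor for Rap activated by cAMP (2:71983023-71984048, intron 1 of 5), by 1.74 ± 0.13 on the log2 scale (edgeR adjusted p = 3.77e-19). Promoters higher in the transgenic line included Adgrg1, an adhesion G protein-coupled receptor (1.02 ± 0.16), Bcr (0.96 ± 0.18), Krt84 (1.00 ± 0.22) and Gm47465 (1.21 ± 0.27), along with intronic or exonic peaks of Kalrn (1.28 ± 0.28), Plekhg1 (1.26 ± 0.24) and Arhgef7 (1.25 ± 0.27). Leaving out 1 library ended the call of Krt84 (knockout control or Firre line at 120 min), Gm47465 (knockout control at 60 min), Kalrn (Firre line at 150 min) and Arhgef7 (Firre line at 120 min), and the call of Adgrg1 ended without the term for time. Lower were peaks at Cep112 (-0.93 ± 0.18), Krt42 (-0.89 ± 0.21) and Myo1g (-0.67 ± 0.11) on chromosome 11, where the median was -0.08 with 24 peaks higher and 113 lower, and at Mir7656 (-0.86 ± 0.23), 4930443O20Rik (-0.66 ± 0.18) and Gm23049 (-0.62 ± 0.15) on other chromosomes. The call of Krt42 ended without the knockout Firre line at 60, 90, 120 or 150 min, and those of Mir7656, 4930443O20Rik and Gm23049 ended in 11, 8 and 2 of the fits that left out 1 library. All 4 calls ended without the knockout control at 30 and 90 min, and those of Mir7656, 4930443O20Rik and Gm23049 also under other settings. Wnt pathway targets were lower as a list (7 of 7 peaks negative, 0 called over all peaks and 2 lower adjusted over the list alone, median -0.18, camera adjusted p = 0.00111; adjusted p = 0.0192 with an estimated correlation). Of those 7 peaks 5 lie on chromosome 11, and the 2 others had a median of -0.17 (unadjusted p = 0.0252, adjusted p = 0.134). With the 3000 bp window and an estimated correlation the list had adjusted p = 0.114. For p53 targets (11 peaks, median 0.09, camera adjusted p = 0.0162; adjusted p = 0.625 with an estimated correlation), 1 peak was called, Cdkn1a, which encodes p21 (0.45 ± 0.12, edgeR adjusted p = 0.0477). No other list passed (smallest adjusted p = 0.0931).

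The count in the knockout background moved with the method and with single libraries. DESeq2 called 153 peaks, loess offsets 2029, the fit without 0 min libraries 672, and that without the knockout control at 30 and 90 min 568. Leaving out the knockout Firre library of 30, 60, 90, 120 or 150 min gave 594, 747, 772, 567 and 554, and leaving out the knockout control of 0, 30 or 120 min gave 751, 656 and 666.

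In the wild type background the Firre line differed from its control at 106 peaks by edgeR, 79 higher and 27 lower. Promoters higher in the Firre line were those of Cd59a, a complement inhibitor (0.88 ± 0.12), Btaf1 (0.75 ± 0.09), Map1b, a microtubule-associated protein (0.70 ± 0.11), and Ankmy1 (0.65 ± 0.12). The calls of Ankmy1 and of the Firre promoter ended with the promoter share as a covariate. A mitochondrial peak at mt-Tr (M:9384-9894) had 1440 ± 261 CPM in the wild type Firre line against 6.82 ± 1.18 in its control, 211-fold. It had 15.9 ± 3.65 CPM in the knockout control and 10.1 ± 2.12 CPM in the knockout Firre line. The mitochondrial peaks beside it had means of 19750 to 30050 CPM in the 4 lines. Reads at mt-Tr were thus nearly absent in the other lines, and whether the difference is one of accessibility was not tested. On chromosome 13, 13 of the 75 tested peaks of 1 Mb were lower, all between 66263176 and 66467273, among them the promoter of 2410141K09Rik (-0.96 ± 0.14). All 7 tested peaks of the unplaced contig JH792827.1 were called higher, with a median of 1.61. The 13 peaks are among the 27 lower calls, and the 7 among the 79 higher calls. Whether these runs of peaks are differences of accessibility was not tested. DESeq2 called 49 peaks, the stricter filter 163 and the promoter covariate 58, and leaving out 1 library gave 70 (wild type control 150 min), 175 (knockout control 150 min) and 179 (wild type Firre line 90 min). No gene list passed (smallest adjusted p = 0.145).

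Of the peaks that differed between Firre and control lines, 12 were higher in both backgrounds and 2 were lower, where independent lists would share 0.45 and 0.093. The backgrounds share no library, but both contrasts used 1 estimate of the spread. Outside Firre, the 10 higher peaks included introns of Rapgef4, Pde6d, Ywhag and Dpf2 and an intergenic peak at -59398 bp from the TSS of Bbs4. At the Rapgef4 peak, the wild type Firre line went from 3.67 CPM at 0 min to 12.4 ± 3.66 CPM (SD, n = 4 times) and the knockout Firre line from 5.26 to 13.9 ± 3.90 CPM (n = 5), while the controls went from 3.68 to 3.62 ± 0.69 and from 2.94 to 3.96 ± 0.61 CPM. At the Pde6d peak, the Firre lines went from 8.66 to 16.0 ± 1.62 CPM and from 10.4 to 18.2 ± 2.33 CPM, and the controls from 11.3 to 8.76 ± 1.03 and from 9.62 to 8.66 ± 0.85 CPM.

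A slope shared by both backgrounds, a test added after the data were seen, called 1 peak by edgeR, 0 by DESeq2 and 1 by limma-voom. An unadjusted p under 0.05 was found at 6334 peaks (4.89%). The peak called by edgeR was the Apod intron peak, 2916 bp from the TSS, with 0.39 ± 0.07 log2 units per hour (edgeR adjusted p = 0.0345). The slopes at Pde6d (0.44 ± 0.09, edgeR adjusted p = 0.118) and Rapgef4 (0.47 ± 0.12, edgeR adjusted p = 0.97) did not pass over all peaks. The count was 0 with DESeq2 size factors or without the filter. It was also 0 in 14 of 23 fits that left out 1 library: the knockout control at 0 or 120 min, the knockout Firre line at 0, 60, 90, 120 or 150 min, the wild type control at 0, 60, 90 or 150 min and the wild type Firre line at 0, 30 or 150 min. It was 2 without the knockout control at 150 min, the wild type control at 30 min or the wild type Firre line at 120 min.

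**Figure D3:**
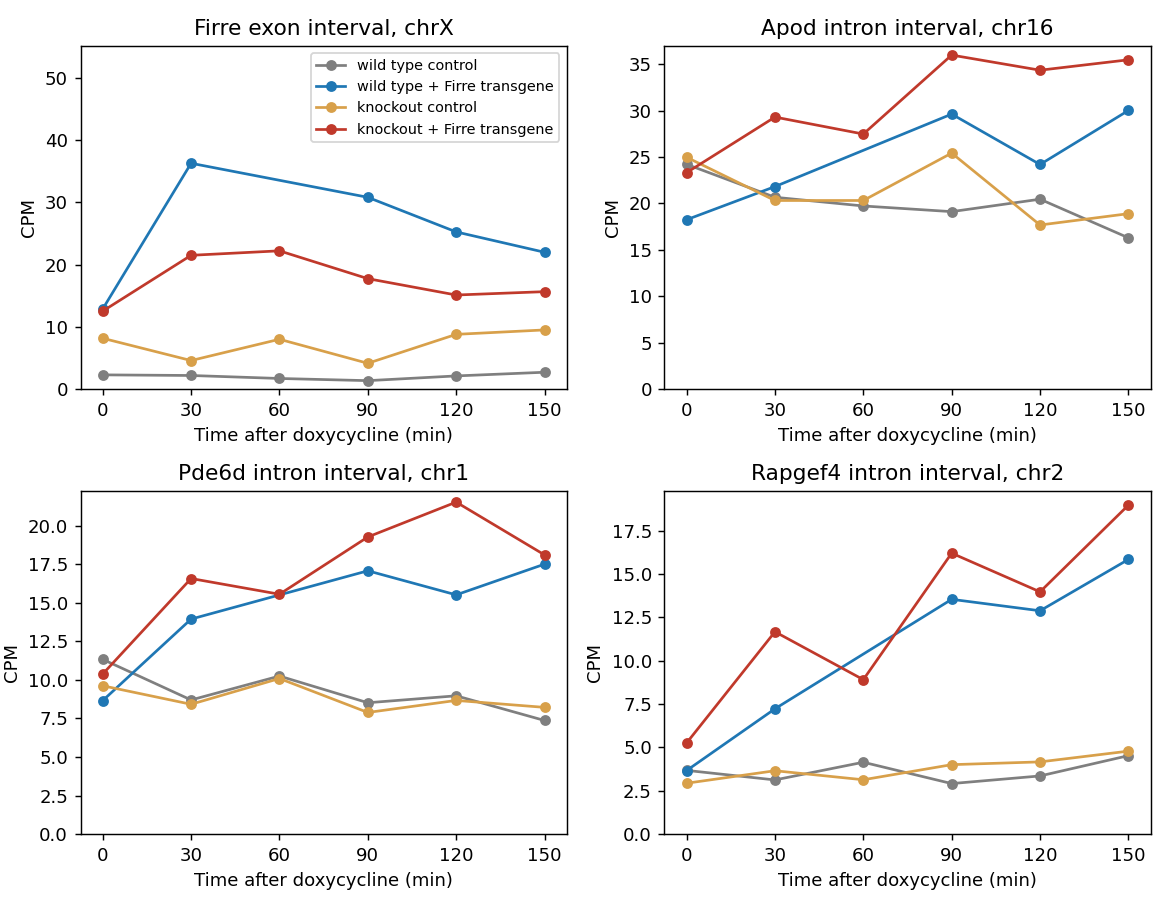
CPM (vertical axes, from 0) against minutes after doxycycline (horizontal axes) for 4 peaks, 1 point per library and 1 line colour per cell line; lines join the libraries of a cell line. In the Firre lines the Rapgef4 peak goes from 3.67 and 5.26 CPM at 0 min to means of 12.4 and 13.9 CPM, while the controls stay near their 0 min values.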

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

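The tests of transgene DNA, of mixed cells, of the 0 min libraries and of chromosome 11, the promoter share covariate, the split of same-sign shares by direction, the shared slope and the difference of line contrasts were chosen only after the results they bear on were seen.

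The exonic Firre peak was higher in the knockout Firre line than in its control, while the other Firre peaks were near 0. Reads from the DNA of the transgene may account for this, if it holds exons without introns (its sequence is not given in the sources used here), since the 15 intron peaks stayed at 0.91% ± 0.20 (SD, n = 6) of the wild type control level. Cells of the knockout Firre line mixed into the knockout control stay open. Whether the knockout control itself holds DNA of the transgene was not tested. Of the transgenic level above the wild type control, the knockout control reached 33.4% at the exonic peak. At 24 other peaks the median was 47.8% (median SE per peak 16.6). These were picked without the knockout control, as higher in both Firre lines than in the wild type control. Of them, 5 were below and 9 above 33.4% by over 2 SE. No share lay between 24.8% (Tead1) and 70.8% (Klf9), so this median describes no peak. At 10:28997735 (99.1%) and 12:72047819 (82.2%) the wild type control held 0 counts, so a high share there need not come from mixed cells. The other 18 Firre peaks, at 1.42 against 3.68 CPM, go with such cells, while the 5 peaks below, among them Pde6d (-4.8%) and Rapgef4 (1.8%), speak against them unless knockout cells without the transgene lie under the wild type control there, which was not measured. Increased accessibility of the transgene after induction stays open. A copy number constant within a line would not account for a rise within that line. The peak went from 12.9 to 28.6 ± 6.30 CPM (SD, n = 4 times) in the wild type Firre line. In the knockout Firre line it went from 12.5 to 18.4 ± 3.27 CPM (n = 5). However, each line had 1 library at 0 min, and DESeq2 did not call the time course.

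At the Apod, Pde6d and Rapgef4 intron peaks, levels after induction were higher in both Firre lines. Library quality as measured by the promoter share is argued against by a slope that was 104.6% (19.8) of its value with that share as a covariate. Other measures of library quality were not tried as covariates. The 0 min libraries as the source of the rise stay open, since the median slope without them was 0.27 log2 units per hour (SE 0.12), which is less than 1 SE above the 0.2 set to exclude them. An effect of Firre stays open too, since the peaks were picked from these libraries; a repeat of the induction in new libraries could decide it. Chance orders of the times cannot be excluded: 4 of 30 orders called at least the 1 peak of the shared slope (highest other 2758) and 13 of 30 that of the time course (highest other 1327), which points to a structure of the samples.

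Between the control lines, 10323 peaks were called, and chance splits of the libraries are excluded, since 1 of 30 splits, the real one, gave as many (highest other 3619, which points to a structure of the samples). Chromosome 11 held 16.3% of the calls, so a change of its own peaks is not the whole cause. Whether part of the cells gained this chromosome was not measured, and effects of a gain on other chromosomes were not tested. Genotype and clone both stay open and untested, with 1 line per genotype. A difference of this pair of lines alone was to be excluded at a same-sign share of 80% or more in the transgenic lines. The share was 80% over all calls outside Firre, 86% for higher and 66.6% for lower calls, against 61.4% for all tested peaks. Of 7127 higher calls 380 were also called higher in the transgenic lines, and of 3177 lower calls 47 were called lower. The higher calls met the mark and the lower calls did not. Chromosome 11 and the promoter share were higher in both knockout lines, so a shared sign cannot tell these sources apart. A difference of this pair therefore stays open. Library quality stays open: with the promoter share as a covariate 0.5% of the calls remained, and that share is higher in both knockout lines. The median of the higher calls went from 0.37 to 0.12 and that of the lower calls from -0.59 to -0.43, while the median SE went from 0.16 to 0.26, so the lower calls kept most of their fold and ended with the wider SE.

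The transgenic line contrasts differed between backgrounds at 345 peaks by a test of the difference itself. No other split of the libraries called as many (1 of 30, highest other 2). However, the other splits mixed libraries of different lines, so line differences entered their spread. They therefore cannot exclude chance for the difference between backgrounds. The count ran from 143 (without the knockout Firre line at 120 min) to 1255 (without the knockout control at 150 min). It was 67 by DESeq2 and 725 with the stricter filter. The 1183 peaks in the knockout background were also exceeded by no other split (1 of 30, highest other 133). For the count of 106 peaks in the wild type background chance cannot be excluded (2 of 30, highest other 351, which points to a structure of the samples). Of these, 12 higher and 2 lower peaks were shared with the knockout background, where independent lists would share 0.45 and 0.093. The higher ones include the exonic and promoter peaks of Firre. Both contrasts used 1 estimate of the spread, so the lists are not fully independent and the overlap cannot exclude chance at single peaks. The wild type Firre library of 90 min had 14977148 counts, far from the next at 8314720. The Gm4869 peak on chromosome 5 had 4.7 CPM in the knockout control at 150 min, far from the next at 2.01 CPM. These were 2 samples far from their group in 48 groups examined, where chance gives about 5%.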

How the results depend on the processing

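The fits without chromosome 11, without the knockout control libraries of 30 and 90 min and with the promoter share as a covariate were chosen after the data were seen; the others were planned. No paired analysis was possible by replicate number, because each line and time has 1 library. The contrasts of lines instead matched libraries by a term for time, and no count of theirs moved by over 1.5 times without it. Correction for GC content was not run. The cause was not tested for any change below, except that fits of the autosomes leave out the Firre peak by construction.

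The Firre time course (1 peak) called 0 by DESeq2 and on autosomes, 4 with loess offsets, 3 with the stricter filter and 8 without the knockout control at 30 and 90 min. The mean Firre response (0) called 1 with total counts, the legacy mode or limma-voom and 2 with loess offsets, the stricter filter or the promoter covariate. The response at 30 min (0) called 1 with total counts, loess offsets or the stricter filter. At 90 min (1) the count was 0 by DESeq2, on autosomes and without the knockout control at 30 and 90 min, and 2 with total counts, loess offsets, the stricter filter, the legacy mode or the covariate. At 150 min (0) it was 1 with total counts, loess offsets, limma-voom or the covariate, 2 with the stricter filter or the legacy mode and 3 without the knockout control at 30 and 90 min. The shared slope (1) called 0 by DESeq2, with DESeq2 size factors or without the filter, and 2 without the knockout control at 30 and 90 min or with the covariate.

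The control lines (10323) differed at 6074 peaks by DESeq2, 6293 with loess offsets, 2134 without the knockout control at 30 and 90 min and 53 with the covariate. The knockout background (1183) gave 153 by DESeq2, 2029 with loess offsets, 568 without the knockout control at 30 and 90 min and 672 without 0 min libraries. The wild type background (106) gave 49 by DESeq2, 163 with the stricter filter and 58 with the covariate. The difference of transgenic line contrasts between backgrounds (345) gave 67 by DESeq2, 693 with loess offsets, 725 with the stricter filter, 215 by limma-voom, 160 without the knockout control at 30 and 90 min, 124 with the covariate and 93 without 0 min libraries. Its higher share of 48.1% was 61.1% under total counts. DESeq2 gave an adjusted p to 74273, 81806, 89339 and 29075 of 129515 peaks in these 4 contrasts.

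Of the 18 Firre peaks called lower, DESeq2 gave an adjusted p to 4 and called all 4 (the other 14 had an unadjusted p of at most 5.13e-13), and the stricter filter kept 5 and called all 5. The chromosome 11 median of 0.14 was 0.052 under total counts and 0.194 with the covariate. The same-sign share of 48.8% was 49.4% with loess offsets. The list tests between the control lines (2) gave 5 with the 3000 bp window, 3 without chromosome 11 and 0 with an estimated correlation. Those in the knockout background (2) gave 1 with an estimated correlation and 1 without chromosome 11, and those in the wild type background (0) gave 1 with the 3000 bp window. With an estimated correlation, no list passed with that window or without chromosome 11.

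Leaving out 1 library at a time gave 0 to 7 for the time course, 0 to 1 for the mean response, 0 to 2 for the shared slope, 0 to 2 for the slope in the knockout background, 0 to 0 for that in the wild type background and for the difference of slopes, 0 to 9 for the control time course and 0 to 0 for the control mean response. It gave 5253 to 17208 between the control lines, 554 to 1491 in the knockout background, 70 to 179 in the wild type background, 18 to 18 Firre peaks and 0.12 to 0.156 for chromosome 11. The difference between backgrounds ran from 143 (without the knockout Firre line at 120 min) to 1255 (without the knockout control at 150 min). It was 561 without the wild type Firre line at 90 min. It was 225, 190 and 205 without the knockout control at 0, 30 and 120 min, and 224 and 172 without the knockout Firre line at 30 and 150 min. It was 171, 197, 184, 181 and 183 without the wild type control at 0, 30, 90, 120 and 150 min, and 147, 202 and 180 without the wild type Firre line at 0, 120 and 150 min. For single named peaks, 2941 of 3116 refitted values kept their side of the threshold and their direction, 164 lost the call, 11 gained one and 0 turned direction. A count of 0 in a library of median size allows up to 0.391 CPM.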

Other observations

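The slope test over 12 peaks was chosen only after the result was seen. Of the 12 peaks outside Firre that differed in the same direction in both backgrounds, 11 had a shared slope after induction in the direction of the line difference, 11 in the knockout and 10 in the wild type background. The median signed slope was 0.32 log2 units per hour (-0.19 to 0.47), and 5 passed when adjusted over these peaks. The mean signed slope per hour was 0.30 in both Firre lines, 0.01 in the wild type control and 0.06 in the knockout control. The difference of 0.26 had a permutation p = 0.0114 (two-sided, 100000 permutations of the times within lines).

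X chromosome medians per library, against the wild type control mean, were 0.16 ± 0.11 (0.01 to 0.32) in the knockout control, 0.15 ± 0.08 in the knockout Firre line and 0.07 ± 0.09 in the wild type Firre line. Besides the peak at 10:28997735-28998078, 3 peaks had 0 counts in the wild type control and counts in the other lines, at 10:27892372, 12:72039803 and 12:72047819. Over the group floor of 0.0700 CPM, the wild type Firre line was at least 27.2-fold higher at the first and at least 15.8-fold, 18.04-fold and 20.4-fold higher at the others. Whether these are differences of accessibility was not tested. The mitochondrial peaks beside mt-Tr did not differ between the wild type lines (edgeR adjusted p = 0.943 and 0.94).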
